A study of Mus musculus with 5 samples.

How the data were processed

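The deposited file held whole-number UMI counts per gene and barcode, made by the authors and deposited as a single matrix. Its values were used as deposited counts, without earlier scaling. Per the labels, reads of 60 and 42 bases came from a NextSeq 2000 and the submitters named the mm10 build. The aligner, the annotation and the way cells were called are not given in the sources used here. The sample tag and antibody-oligo libraries were not analysed here.

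Barcodes with at least 200 UMIs, at least 100 genes and under 20% mitochondrial UMIs were kept, which left out 847 barcodes of YO1 (4.16%) and 505 of YO2 (2.85%). The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 gave 32 clusters with leidenalg 0.10.2. Of these, 28 had at least 20 cells. A cluster took the name of the fixed marker list with the most markers among its 10 defining genes, if these were at least 2 and the list's score was within 0.5 of the highest. Otherwise it took the list with the highest score if no list had more markers there. A name needed at least 3 of its markers in at least 20% of the cells. Clusters 11, 25 and 27 were named with 0 markers among the defining genes and clusters 12, 13 and 21 with 1, and clusters 3 and 23 took a name other than that of their highest score. Scrublet was run with an expected doublet rate of 6%. Shares carry exact Clopper-Pearson intervals.

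UMIs were summed per pool and cluster where at least 30 cells were present. The sums were fitted with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, pool as a block, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. DESeq2 1.42.0 and limma 3.58.1 were used for alternatives. Gene lists were tested with limma camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, for lists with at least 5 tested members. Camera and fry used log CPM with a prior count of 2. Genes named by size were the 10 highest and the 10 lowest log2 changes among genes with adjusted p under 0.05 and an average of at least 20 CPM, gene models, ribosomal and mitochondrially encoded genes skipped. Pools were compared by the ratio of CPM with a pseudocount of 1 CPM, over genes with at least 100 UMIs, with 95% counting intervals. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

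The filters, 21 gene lists, 23 marker lists, the named-gene rule, the tests and most of the other settings compared were chosen before the data were examined. Chosen after the data were seen were the rule for naming clusters, cluster 1 as the reference, the omission from each contrast of variable genes, of defining genes of its clusters and of naming markers, the minimum of 400 cells for the comparison within clusters, and the settings named as added. The planned comparisons of ages, of tissues and of their interaction, class shares by tissue, and antibody-oligo values were not run, because barcodes carried only the pool.

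The fit was tested on simulated data: of 100 genes changed by log2 1, edgeR recovered 95 for cluster 4 and 89 for cluster 8, and it called 12 of 7489 and 9 of 7501 unchanged genes. These simulated sums had the same mean profile in all clusters and pools, 200 changed genes and the fitted spread. They do not cover contrasts in which many genes change or the pools disagree. The counting interval held the true ratio for 95.3% of 11466 unchanged genes in simulated Poisson counts, which the interval assumes. Gene positions are those of GRCm38.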

Results

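Neutrophils were sorted as DAPI-negative cells positive for CD11b and Ly6G from blood, bone marrow, lung, liver, spleen and intestine of young and old C57BL/6 mice at steady state, a common inbred laboratory strain. The series asks how neutrophils differ between tissues. Single-cell whole-transcriptome libraries were made on the BD Rhapsody system, which captures cells in microwells and tags each mRNA molecule with a unique molecular identifier (UMI). The experiment was repeated, and the samples of each round were multiplexed in their own cartridge, which gave 2 pools, named YO1 and YO2 after the labels. Young mice were 10 weeks old by the sample labels and 8 weeks old by the design text, and old mice were 20 months old. Each pool held young and old cells. The cell barcodes carried the name of the pool but neither tissue nor age, so no comparison of tissues or of ages was analysed here. The comparisons are of cell clusters with each other and of the pools.

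The count matrix held 21995 genes and 38072 barcodes. The YO1 pool had 20352 barcodes with 39713846 UMIs and a median of 1189 UMIs and 634 genes per barcode. The YO2 pool had 17720 barcodes with 41839786 UMIs and a median of 1444 UMIs and 723 genes. After removal of barcodes with few UMIs or a high mitochondrial share, 19505 cells of YO1 and 17215 cells of YO2 remained, with medians of 1231 and 1454 UMIs. The smallest kept cell had 200 UMIs in YO1 and 496 in YO2, and 547 cells of YO1 against 1 of YO2 had fewer than 500 UMIs. With 1 library per pool, values that compare the pools carry counting intervals only and no test.

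Neutrophils made up most of the sorted cells in each pool. Of 28 clusters with at least 20 cells, 10 scored at least 1.0 higher on a neutrophil marker list than on any list of another cell type, the cycling list left aside, with fewer than 2 markers of another type among their 10 leading genes. They held 74.8% of YO1 cells (95% exact interval 74.2 to 75.4) and 78.0% of YO2 cells (77.4 to 78.6). The other 18 clusters did not meet this rule although the sort required Ly6G. Most of them scored highest on another cell type, but cluster 26 scored highest on the secondary-granule neutrophil list and cluster 27 on the cycling list. The depth of the pools differed, with medians of 1231 and 1454 UMIs per cell, and no cells were removed as doublets, because the Scrublet threshold marked 0 cells in YO1 and 4 in YO2. Intervals and ratios of shares cover the counting of cells, not differences between animals.

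The neutrophil clusters were divided unevenly between the pools. Cluster 1, the largest, was marked by Tnfsf14, Scnn1a and Slc40a1 and held 9.20% of YO1 (8.80 to 9.62) and 23.3% of YO2 (22.7 to 23.9). Cluster 4, set apart by the interferon-induced genes Ifit1, Rsad2 and Isg15, held 5.60% of YO1 (5.28 to 5.93) and 9.54% of YO2 (9.10 to 9.99). Cluster 8 was marked by Il1a, Ccrl2, Nr4a3, Cxcl2 and Icam1, genes of the response to inflammatory signals. It held 0.502% of YO1 (0.408 to 0.612) and 9.13% of YO2 (8.70 to 9.57), an 18.2-fold higher share in YO2. Clusters 5, 7, 14 and 3 went the other way. Cluster 5, marked by Gpr27, Mmp8, Retnlg and Mmp25, held 11.1% of YO1 (10.7 to 11.6) and 0.802% of YO2 (0.674 to 0.946), a 13.9-fold higher share in YO1. Cluster 7, marked by the secondary granule genes Ltf and Ngp and by Ly6g, held 7.66% of YO1 (7.30 to 8.05) and 2.34% of YO2 (2.12 to 2.58). Cluster 14, a cycling cluster marked by Mki67, Top2a and the azurophil granule proteases Elane and Prtn3, held 3.99% of YO1 (3.72 to 4.27) and 0.401% of YO2 (0.312 to 0.507). Elane was seen in 24.3% of its cells and Prtn3 in 27.6%, against 93.4% for Mki67. Cluster 3, marked by Stfa2l1 and Asprv1, held 16.0% of YO1 (15.5 to 16.6) and 5.69% of YO2 (5.35 to 6.05). Since YO2 supplied 94.1% of cluster 8 and YO1 supplied 94.0% of cluster 5 and 91.9% of cluster 14, these clusters mark a pool as well as a kind of cell. The shares depended on the settings, with clusters matched by the overlap of their cells. Cluster 7 held 3.80% of YO1 and 0.953% of YO2 at a Leiden resolution of 1.5, and cluster 4 held 3.55% and 5.23% with an equal minimum of UMIs. Cluster 5 held 6.74% and 0.444% without the highest doublet scores, and in each of these the same pool had the higher share.

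**Figure D1:**
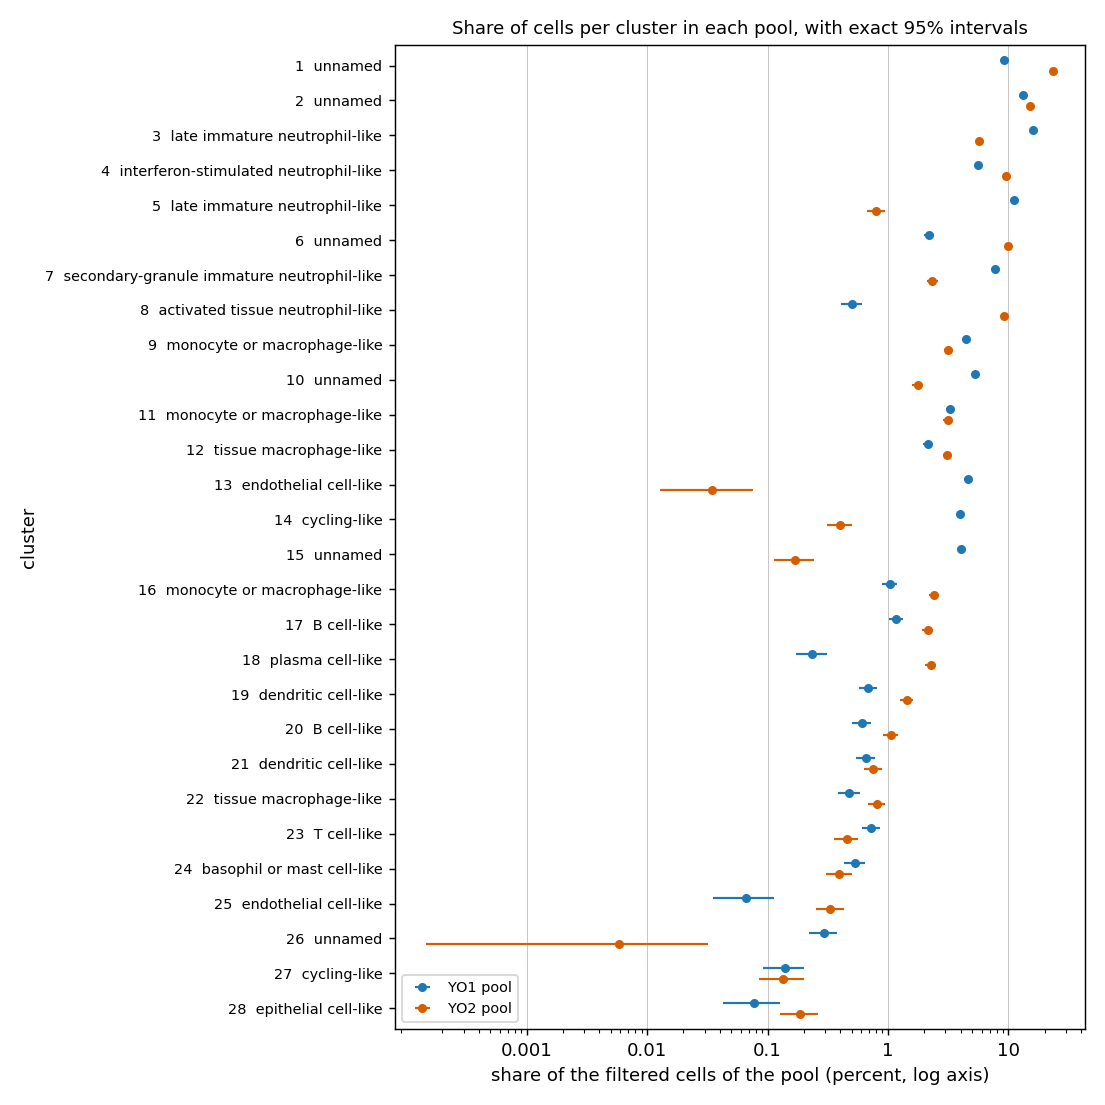
Share of cells in each of 28 clusters in the YO1 and YO2 pools, in percent on a logarithmic axis, with exact 95% intervals for the counting of cells. Clusters 5, 13, 14, 15 and 26 lay higher in YO1 and clusters 8 and 18 higher in YO2, by between 9.58-fold and 131-fold.

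Some clusters of other cell types were divided unevenly as well, and others were close to even. Cluster 13 scored highest on the endothelial list, was marked by Clec4g, Oit3 and Stab2, and held 892 cells of YO1 and 6 of YO2, or 4.57% (4.28 to 4.88) against 0.0349% (0.0128 to 0.0758). Its 6 cells of YO2 held 0 UMIs of these 3 genes. Cluster 15, unnamed by the marker rule but with the eosinophil genes Ccr3 and Alox15 among its leading genes, held 792 and 29 cells. Plasma cells, which secrete antibody, formed cluster 18, marked by Jchain, Igha and Igkc, with 46 cells of YO1 (0.236%, 0.173 to 0.314) and 389 of YO2 (2.26%, 2.04 to 2.49). Monocytes and macrophages in clusters 9, 11 and 12 held 4.46%, 3.25% and 2.15% of YO1 and 3.18%, 3.14% and 3.10% of YO2. B cells in cluster 17 held 1.16% and 2.13%. Cluster 28, which scored highest on the epithelial list, held 15 cells of YO1 with 0 UMIs of the lung surfactant gene Sftpc and 32 cells of YO2 with 11305. Of the cells in cluster 26, 96.6% were among the highest doublet scores, as were 39.9% of those in cluster 20 and 6.95% of those in cluster 8.

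Differences between neutrophil clusters were measured as the change from cluster 1, the largest, in 6 contrasts over 8275 to 8282 genes, on UMIs summed per pool and cluster. Each cluster gave 1 sum per pool, and the edgeR fit used 20 sums of 10 clusters with pool as a block. Its errors measure how far differences between clusters disagreed between these 2 pools, taken over all 10 clusters. They do not measure spread between single animals. Variable genes used for clustering, the 10 leading genes of the cluster and of cluster 1, and the markers of the cluster's name were not tested in its contrast. Leading genes of other clusters were tested, such as Ngp and Gpr27, and genes of the same programmes move with the clustering, so these contrasts describe the clusters without testing that they exist. Genes named for the size of their change passed, averaged at least 20 CPM over the sums, and were neither numbered gene models nor ribosomal or mitochondrially encoded genes. Genes outside this limit reached larger changes in each contrast but that of cluster 3. Without the pool as a block the counts of genes higher and lower were 0 and 0 for cluster 3, 49 and 0 for cluster 4, 1065 and 769 for cluster 5, 1973 and 1578 for cluster 7, 676 and 680 for cluster 8, and 3055 and 2356 for cluster 14. Of 106 tests of a gene list in a contrast, limma camera with the preset correlation of 0.01 passed 43, fry passed 47, and camera passed 0 with an estimated correlation (adjusted p from 0.108 to 0.988). Median, mean and camera differed in sign in 19 of the 106 tests, none of them among the 43.

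Interferon-inducible genes were among those higher in cluster 4 than in cluster 1. Irgm1, an interferon-inducible GTPase (chromosome 11, 48861968 to 48871683, minus strand, protein-coding), was higher by log2 2.51 ± 0.14 (SE; edgeR adjusted p = 5.1e-12) and stood at 168 CPM against 26.3 CPM in YO1 and 188 CPM against 35.6 CPM in YO2. Eif2ak2, the kinase that halts translation on sensing double-stranded RNA, was higher by 2.55 ± 0.21, Ifih1, a cytosolic RNA sensor, by 2.29 ± 0.27, and Rnf213, a ubiquitin ligase, by 2.40 ± 0.14. Mitd1 (2.62 ± 0.25), Parp14 (2.20 ± 0.16), Trafd1 (2.03 ± 0.13), Helz2 (2.03 ± 0.21), Ifi35 (1.68 ± 0.24) and Csrnp1 (1.64 ± 0.30) completed the 10 largest rises among genes averaging at least 20 CPM. The 2 lowest named genes were Elovl1, an elongase of very long fatty acids, at -0.65 ± 0.16 (edgeR adjusted p = 0.033), and Slc43a2, an amino acid transporter, at -0.62 ± 0.15 (edgeR adjusted p = 0.028).

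In all, edgeR called 103 genes higher and 4 lower in cluster 4. All 4 tested members of the interferon-stimulated list were higher, including Xaf1 (2.96 ± 0.26), Bst2 (2.35 ± 0.31) and Ifitm3 (1.44 ± 0.19), and the count was the same when adjusted over the list alone; the cluster was named by other members of that list, so the direction is not independent. Of 15 MHC class I genes, 7 were higher and 8 did not pass, against 12 higher when adjusted over the list alone, with a median of 0.75 (limma camera adjusted p = 1.93e-18). The list's adjusted p = 0.108 with an estimated correlation. Tap1 (1.35 ± 0.12), a peptide transporter, Nlrc5 (1.72 ± 0.26), the transactivator of the class I genes, and Psmb8 (0.98 ± 0.16), an immunoproteasome subunit, were higher, and these 3 genes were chosen after their values were seen. B2m at 0.32 ± 0.16 and H2-K1 at 0.47 ± 0.21 did not pass. Of 12 immediate early genes 1 passed over all genes and 3 adjusted over the list alone (median 0.42; limma camera adjusted p = 0.00121). Its adjusted p = 0.362 with an estimated correlation. Camera with the preset correlation also passed the NF-kB, glycolysis, phagocytosis and apoptosis lists upward and the ribosomal list downward, of which the apoptosis, glycolysis and phagocytosis medians (0.17, 0.13 and 0.09) turned to 0 or lower with total UMIs, with adjusted p = 0.354, 0.391, 0.349, 0.316 and 0.626 with an estimated correlation. Scaling by total UMIs moved the median of all genes from -0.02 to -0.18. The number of genes higher fell to 34 without the YO2 sum of cluster 1, 52 without the YO1 sum of cluster 4, 56 without the YO1 sum of cluster 1 and 67 without the YO2 sum of cluster 4, and the 4 lower genes were lost in each (edgeR 0 lower, 103 to 210 at unadjusted p under 0.05).

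In cluster 8 against cluster 1, Bcl2a1b had the largest rise among the tested genes averaging at least 20 CPM. Bcl2a1b, one of several near-identical mouse genes for the anti-apoptotic protein A1 (chromosome 9, 89199209 to 89207827, plus strand, protein-coding), was higher by log2 4.80 ± 0.32 (edgeR adjusted p = 2.6e-10), at 233 CPM against 6.35 CPM in YO2 and 115 CPM against 9.47 CPM in YO1. Il2rg, the common cytokine receptor gamma chain, was higher by 3.28 ± 0.26, Sod2, the mitochondrial superoxide dismutase, by 2.59 ± 0.18, and Ptgs1, a cyclooxygenase, by 2.49 ± 0.20. Rhoh (3.21 ± 0.37), Ptpn7 (3.21 ± 0.38), Hvcn1 (3.08 ± 0.44), Mif (2.54 ± 0.32) and Mapk6 (2.48 ± 0.29) were also among the 10 largest rises. The lowest were Cep19 (-2.70 ± 0.25), the sphingosine phosphate receptor gene S1pr4 (-2.63 ± 0.38; edgeR adjusted p = 1.2e-05), Asb7 (-2.60 ± 0.29), AI467606 (-2.56 ± 0.21), Stk39 (-2.55 ± 0.64), Tnfaip8l2 (-2.46 ± 0.18), Nhsl2 (-2.44 ± 0.24), Mgam (-2.34 ± 0.25), Ccdc125 (-2.22 ± 0.45) and Ankrd22 (-2.18 ± 0.36).

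All 12 tested NF-kB response genes were higher in cluster 8, and all 12 when adjusted over the list alone (median 1.29, limma camera adjusted p = 7.55e-11). Il1b (1.56 ± 0.35), Tnfaip2 (1.27 ± 0.19) and Birc3 (1.31 ± 0.15) were among them. The cluster was named by other members of that list, so the direction is not independent. The list's adjusted p = 0.108 with an estimated correlation. Of 17 trafficking receptors 8 were lower and 9 did not pass (median -0.54), among them the chemokine receptor gene Cxcr2 (-1.08 ± 0.22) and the selectin ligand gene Selplg (-1.11 ± 0.20), with adjusted p = 0.354 with an estimated correlation. Of 7 secondary granule genes 3 were lower, Hp (-1.31 ± 0.21) and Pglyrp1 (-1.01 ± 0.21) among them, with adjusted p = 0.362 with an estimated correlation. Of 16 apoptosis and survival genes 8 were higher and 3 lower, with adjusted p = 0.362 with an estimated correlation. They had opposite known actions: Bcl2a1a (4.71 ± 0.39) opposes cell death and was higher, as was Bax (1.42 ± 0.26), which promotes it, while Bid (-1.99 ± 0.20), which also promotes it, was lower; Bcl2a1a and Bid were chosen after their values were seen. Of 6 p53 and senescence genes 4 were higher, with adjusted p = 0.267 with an estimated correlation, among them Ccng1 (1.18 ± 0.18) and Mdm2 (0.44 ± 0.15). Of 7 heat shock genes 5 were higher, with adjusted p = 0.296 with an estimated correlation, including Hspa5 (0.68 ± 0.22), a chaperone gene of the endoplasmic reticulum. MHC class I had 8 higher and 1 lower of 15, with adjusted p = 0.375 with an estimated correlation. Immediate early genes had 4 higher of 12 and 5 when adjusted over the list alone, without a call for the list. The other lists above kept their counts when adjusted over the list alone, except MHC class I with 8 higher and 2 lower. Of 7 NADPH oxidase and antimicrobial genes 1 was higher, Ncf1 (1.35 ± 0.24), and 3 lower, among them S100a8 (-1.21 ± 0.19). Only 3 mitochondrially encoded genes were tested, too few for a list test, and all 3 were higher (median 1.81). The comparison of pools within clusters measured 11, so these 3 do not stand for the group.

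The cluster 8 contrast rested on the YO2 pool. It had 1076 genes higher and 1105 lower, but without the YO2 sum of cluster 8, which left 98 cells of YO1, edgeR called 49 higher and 65 lower, and without the YO2 sum of cluster 1 it called 457 and 526. Of the 2181 called genes, 421 changed in opposite directions in the 2 pools, Bax (-0.22 in YO1, 1.56 in YO2) and Ccng1 (-0.47 in YO1, 1.21 in YO2) among them. Bcl2a1b, Il2rg, Rhoh, Sod2, Mapk6, AI467606 and Tnfaip8l2 still passed without the YO2 sum of cluster 8, and 12 of the 20 genes with the largest changes did not. Of the genes of cluster 8 whose changes are given here, 21 lost their call without that sum and 2, Bax and Ccng1, changed sign. The median of all genes was 0.03, 0.13 with DESeq2, -0.08 with the mean over cells and -0.50 without the YO2 sum of cluster 8.

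Granule and surface genes were among the largest rises in cluster 5 against cluster 1. Ngp, the neutrophilic granule protein gene (chromosome 9, 110419747 to 110423012, plus strand, protein-coding), was higher by log2 7.28 ± 0.59 (edgeR adjusted p = 4.8e-10), and Cd177, a surface glycoprotein of neutrophils, by 5.04 ± 0.22. Acvrl1, a receptor of the TGF-beta family, was higher by 6.02 ± 0.32, Mgst2, a microsomal glutathione transferase, by 4.82 ± 0.22, and Hvcn1, the voltage-gated proton channel, by 4.03 ± 0.38. Cldn15 (4.07 ± 0.36), Anxa3 (3.98 ± 0.24), Tst (3.94 ± 0.32), Pabpc1l (3.83 ± 0.26) and Olfml2b (3.57 ± 0.31) followed. Among genes averaging at least 20 CPM, the lowest were Amz1 (-4.52 ± 0.37), Ggct (-3.60 ± 0.54), Gpr35 (-3.46 ± 0.37), Prr5l (-3.42 ± 0.29), Bri3bp (-3.09 ± 0.40), the integrin gene Itga4 (-3.05 ± 0.23), the transcription factor gene Batf (-3.00 ± 0.40), the lysosomal carboxypeptidase gene Ctsa (-2.83 ± 0.22), Anp32e (-2.79 ± 0.67) and Metrnl (-2.76 ± 0.29).

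Of 6 secondary granule genes 5 were higher in cluster 5, and all 6 when adjusted over the list alone (median 2.88; limma camera adjusted p = 4.43e-05). That list's adjusted p = 0.133 with an estimated correlation. Of 26 hypoxia and glycolysis genes 15 were higher and 2 lower, as when adjusted over the list alone (median 0.52), but 9 higher and 7 lower with total UMIs (median 0.16), among them Gpi1 (1.14 ± 0.15), Aldoa (0.81 ± 0.16) and Pkm (0.73 ± 0.15), with adjusted p = 0.296 with an estimated correlation. Of 7 NADPH oxidase and antimicrobial genes 5 were higher and 1 lower, or 3 and 1 with total UMIs, including S100a8 (1.91 ± 0.20) and Ncf1 (1.54 ± 0.24), with adjusted p = 0.267 with an estimated correlation. Tertiary granule genes were higher in 3 of 6 (median 0.51), Fpr2 (1.88 ± 0.25) and Itgam (1.22 ± 0.15) among them, but 3 higher and 3 lower with total UMIs (median 0.16). Of 12 NF-kB response genes 1 was higher and 6 lower, or 8 lower when adjusted over the list alone, with adjusted p = 0.296 with an estimated correlation, and of 12 immediate early genes 9 were lower, or 10 when adjusted over the list alone, with adjusted p = 0.362 with an estimated correlation. Il1b (-2.30 ± 0.36), the gene for a main inflammatory cytokine, and the AP-1 gene Junb (-1.50 ± 0.27) were examples. Csf3r, the receptor gene for the growth factor G-CSF, was at -1.69 ± 0.23, and Mcl1, a survival factor gene, at -0.98 ± 0.23; of their apoptosis and survival list 2 were higher and 8 lower of 16. Heat shock genes had 3 lower of 7, or 5 when adjusted over the list alone, with adjusted p = 0.244 with an estimated correlation, and ribosomal protein genes 38 lower of 72, or 1 higher and 44 lower when adjusted over the list alone, with adjusted p = 0.391 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes were higher in 12 of 50, with a median of 0.19 that turned to -0.18 with total UMIs (6 higher and 13 lower), and adjusted p = 0.66 with an estimated correlation.

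In cluster 5 edgeR called 1340 genes higher and 1053 lower with TMM. With total UMIs the split turned to 808 higher and 2281 lower, as the median of all genes moved from -0.04 to -0.39. Without the YO1 sum of cluster 5, which left 138 cells of YO2, 435 were higher and 193 lower with a median of -0.31, and Ggct, Gpr35, Bri3bp, Anp32e and Mcl1 no longer passed; without the YO2 sum of cluster 1 the counts were 885 and 575, and without its YO1 sum 673 were lower.

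In cluster 7 against cluster 1, several of the genes with the largest changes in cluster 5 also changed, and no test compared these 2 clusters with each other. Hvcn1 was higher by log2 6.13 ± 0.29 (edgeR adjusted p = 1.3e-14), Mgst2 by 6.03 ± 0.19, Acvrl1 by 6.02 ± 0.30, Gpr27 by 5.89 ± 0.35, Tmem216 by 5.32 ± 0.16 and Anxa3 by 5.03 ± 0.20, ahead of Cldn15 (4.84 ± 0.32), Slc17a9 (4.60 ± 0.26), Kcnab2 (4.52 ± 0.23) and Rhou (4.51 ± 0.14). At an average of at least 20 CPM, the lowest were Sirpb1b (-3.96 ± 0.23), Otulinl (-3.63 ± 0.33), Prr5l (-3.62 ± 0.26; chromosome 2, 101714285 to 101883027, minus strand, protein-coding), Gpr35 (-3.61 ± 0.31), Amz1 (-3.58 ± 0.28), the cytokine receptor gene Il13ra1 (-3.47 ± 0.26), Arl4c (-3.41 ± 0.28), Sirpb1c (-3.39 ± 0.24), Pla2g7 (-3.35 ± 0.24), which encodes a secreted phospholipase, and Metrnl (-3.32 ± 0.26). Acvrl1, Mgst2, Hvcn1, Cldn15, Anxa3, Amz1, Gpr35, Prr5l and Metrnl were also among the genes named by size for cluster 5.

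Of 18 trafficking genes 5 were higher and 11 lower in cluster 7, as when adjusted over the list alone, including Selplg (-2.28 ± 0.20) and Cxcr2 (-1.98 ± 0.22); the list did not pass camera. Of 12 immediate early genes 11 were lower (median -1.88; limma camera adjusted p = 9.2e-06), Junb (-2.62 ± 0.27) among them, with adjusted p = 0.296 with an estimated correlation. NF-kB response genes had 1 higher and 9 lower of 12, or 10 lower when adjusted over the list alone, with Il1b at -2.81 ± 0.36 and adjusted p = 0.296 with an estimated correlation. MHC class I genes had 11 lower of 15, H2-D1 at -1.48 ± 0.18, with adjusted p = 0.354 with an estimated correlation, and apoptosis and survival genes 4 higher and 9 lower of 16, Csf3r at -2.81 ± 0.23, with adjusted p = 0.354 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had 32 higher and 3 lower of 50 (median 0.61; limma camera adjusted p = 1.26e-05), with adjusted p = 0.391 with an estimated correlation. Primary granule genes were higher in 2 of 3, Ms4a3 (5.13 ± 0.87) and Cd63 (1.74 ± 0.20), as were 2 of 3 secondary granule genes, most of that list not being tested because it formed or named clusters. Only 3 mitochondrially encoded genes were tested, and all 3 were higher (median 2.34), which again does not cover the group. Tertiary granule genes had 2 higher and 3 lower of 7. Cell cycle genes were higher in 6 of 15. Cluster 7 had 2282 genes higher and 1888 lower with TMM and 1869 and 2268 with total UMIs, the median of all genes being 0.10, -0.07 with total UMIs and 0.21 with DESeq2.

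Genes of mitosis were among the largest rises in cluster 14 against cluster 1. Cenpe, a kinetochore motor gene, was higher by log2 9.35 ± 0.49 (edgeR adjusted p = 5.7e-14), and Cdca8 (8.16 ± 0.39), Smc2 (7.80 ± 0.39), Tpx2 (7.76 ± 0.35), Prc1 (6.39 ± 0.35) and Ccnb2 (5.84 ± 0.30), which act in mitosis, followed, as did Nucks1 (5.10 ± 0.33). These follow from the cell cycle markers that named the cluster. Outside the cell cycle, Orm1, an acute-phase glycoprotein also stored in granules, was higher by 8.55 ± 0.37, Ngp by 8.30 ± 0.61 and Hvcn1 by 5.78 ± 0.31. With the same minimum of 20 CPM, the lowest were Prr5l (-5.89 ± 0.34), Sirpb1b (-5.54 ± 0.28), Pla2g7 (-5.45 ± 0.29), Il13ra1 (-5.43 ± 0.34), the arginase gene Arg2 (-5.18 ± 0.27), Amz1 (-5.15 ± 0.34), Cd300ld (-5.12 ± 0.31), the aquaglyceroporin gene Aqp9 (-5.04 ± 0.24), Sirpb1c (-4.96 ± 0.29) and Trim30b (-4.91 ± 0.30).

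All 8 tested cell cycle genes were higher in cluster 14 (median 7.49), with adjusted p = 0.133 with an estimated correlation. Of 7 secondary granule genes 4 were higher and 1 lower, with adjusted p = 0.356 with an estimated correlation, while of 7 tertiary granule genes 6 were lower, Mmp9 (-2.93 ± 0.23) among them, with adjusted p = 0.296 with an estimated correlation. Of 18 trafficking genes 3 were higher and 14 lower, Cxcr2 at -4.25 ± 0.24, with adjusted p = 0.296 with an estimated correlation. Phagocytosis genes had 1 higher and 10 lower of 12 and adjusted p = 0.133 with an estimated correlation, immediate early genes 1 higher and 11 lower of 12 and adjusted p = 0.325 with an estimated correlation, and NF-kB response genes 9 lower of 12 and adjusted p = 0.296 with an estimated correlation. Apoptosis and survival genes had 3 higher and 11 lower of 16, Csf3r at -4.59 ± 0.26 and Mcl1 at -3.66 ± 0.25, and adjusted p = 0.316 with an estimated correlation. MHC class I genes had 1 higher and 11 lower of 15, H2-D1 at -2.70 ± 0.19, and adjusted p = 0.362 with an estimated correlation, while all 3 tested MHC class II genes were higher, H2-DMa at 2.47 ± 0.39. Ribosomal protein genes had 54 higher and 5 lower of 72 and adjusted p = 0.418 with an estimated correlation, and oxidative phosphorylation genes 37 higher and 5 lower of 50 and adjusted p = 0.509 with an estimated correlation. Only 3 mitochondrially encoded genes were tested, and all 3 were higher (median 3.37), which does not cover the group. All these counts were the same when adjusted over the list alone. The medians of the glycolysis (-0.28), lipid handling (-0.22), heat shock (-0.08) and senescence (-0.08) lists changed sign with total UMIs and with DESeq2. Cluster 14 may also hold cells other than neutrophils. Its YO1 sum held Igkc at 812 CPM, against at most 381 CPM (cluster 8) in the other neutrophil clusters of YO1. Only 16.5% of its YO1 cells had an Igkc UMI. The MHC class II rise is therefore not assigned to neutrophils here.

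Cluster 14 had 3275 genes higher and 2581 lower with TMM, 4035 and 1893 with total UMIs and 3719 and 1737 with DESeq2. The median of all genes moved from 0.24 to 0.62 and 0.63, and DESeq2 changed the test as well as the scaling. Without the YO1 sum of cluster 14, 2004 were higher and the median was -0.02. Its 778 cells of YO1 held 9535 Elane and 8500 Mpo UMIs, and its 69 cells of YO2 held 1 Elane and 0 Mpo UMIs. Of its 5856 called genes, 142 differed in direction between the pools.

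Few genes passed between cluster 3 and cluster 1. Asb7 (0.97 ± 0.15; edgeR adjusted p = 0.01), the mast cell immunoglobulin-like receptor gene Milr1 (0.91 ± 0.16), Scrg1 (0.86 ± 0.15) and Mindy1 (0.62 ± 0.12) were higher and the histone chaperone gene Nap1l1 was lower (-0.85 ± 0.17; edgeR adjusted p = 0.046), the 5 genes that passed. No member of a fixed list passed over all genes with edgeR. Adjusted over the list alone, 4 of 26 glycolysis genes were higher, 1 of 6 secondary granule, 1 of 6 tertiary granule and 1 of 7 NADPH oxidase and antimicrobial genes were higher, 2 of 5 interferon-stimulated genes were lower, and trafficking genes were 2 higher and 1 lower of 18. Cd177 at 1.11 ± 0.26 and S100a8 at 0.82 ± 0.19 did not pass over all genes. Camera passed the glycolysis list with the preset correlation (median 0.28; limma adjusted p = 2.51e-07), with adjusted p = 0.133 with an estimated correlation. It also passed the secondary granule, tertiary granule and NADPH oxidase lists upward and the MHC class I list downward, with adjusted p = 0.267, 0.316, 0.267 and 0.418 with an estimated correlation. The 5 calls were lost without the pool as a block, and with each of the 4 sums left out in turn, when edgeR called 0 genes (152 to 217 higher and 136 to 202 lower at unadjusted p under 0.05); DESeq2 on all sums called 14 higher and 1 lower. Scaling by total UMIs moved the median of all genes from -0.01 to -0.16 and left 0 higher and 1 lower with edgeR (129 and 642 at unadjusted p under 0.05).

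**Figure D2:**
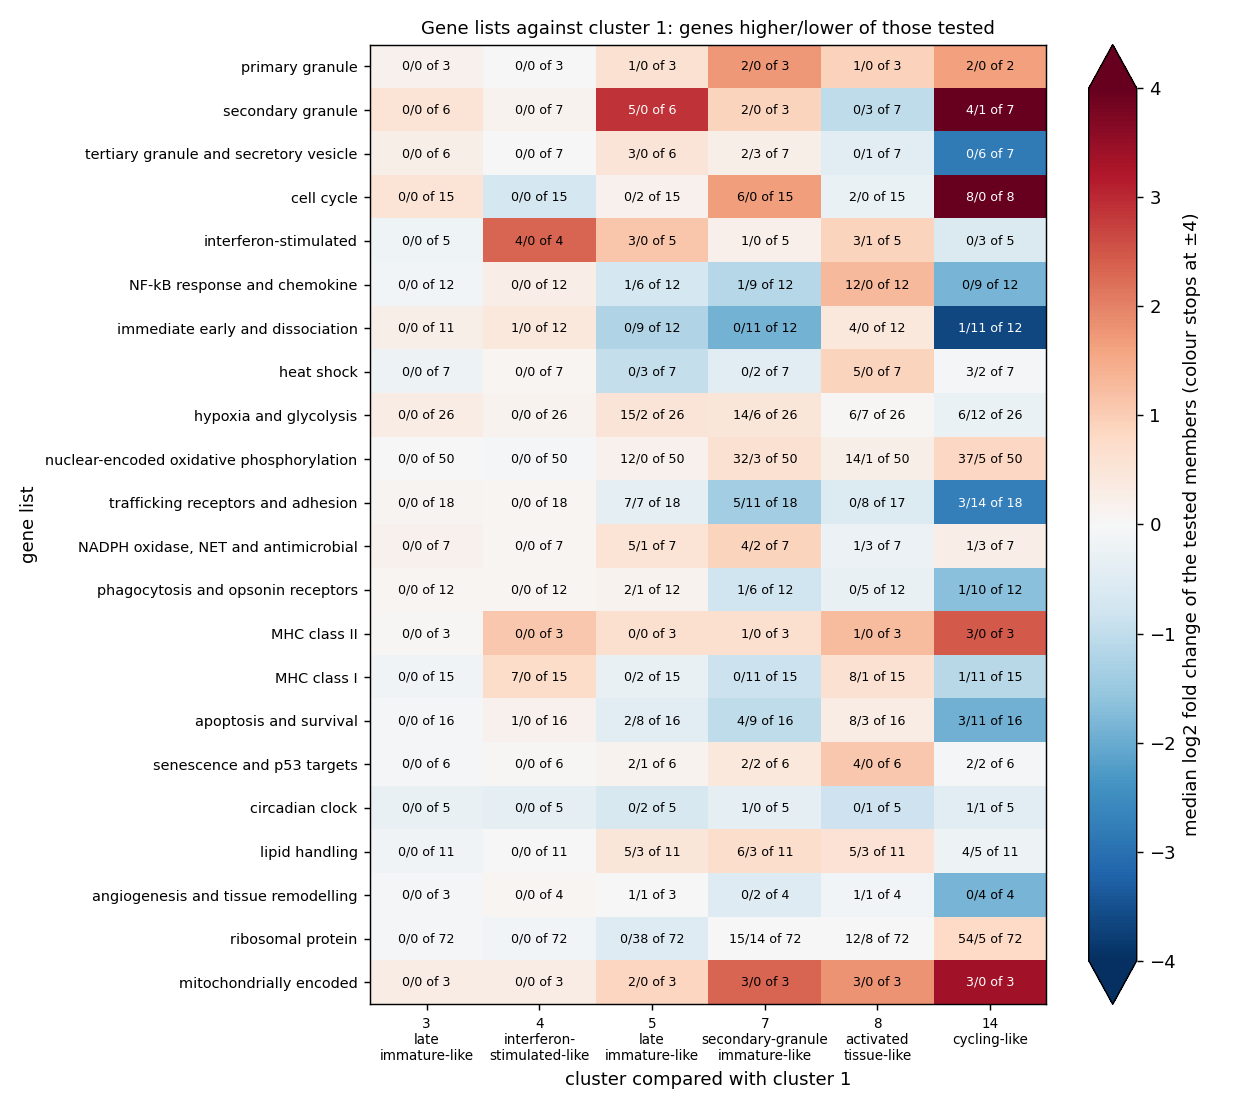
Median log2 change from cluster 1 of each fixed gene list, with ribosomal and mitochondrially encoded genes, in clusters 3, 4, 5, 7, 8 and 14, with the numbers of genes higher and lower of those tested in each cell. NF-kB response genes were higher in cluster 8 (12 of 12), which was named by other members of that list. The medians of the NF-kB response and immediate early lists were below 0 in clusters 5, 7 and 14.

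The pools themselves differed most in transcripts of a few cell types. Of 11681 genes with at least 100 UMIs, 122 were at least 4-fold higher in YO2 and 224 at least 4-fold higher in YO1, with a pseudocount of 1 CPM; these are values of 2 libraries without a test, and gene models, ribosomal and mitochondrially encoded genes are not named. The myeloid granule genes Mpo (chromosome 11, 87793581 to 87804413, plus strand), at log2 -7.63 (95% counting interval -7.74 to -7.43; 8719 UMIs in YO1 and 5 in YO2), and Elane (chromosome 10, 79886247 to 79888215, plus strand), at -7.57 (-7.74 to -7.34), were lowest in YO2 relative to YO1 with this pseudocount. The endothelial genes Clec4g (-7.44; 10597 and 23 UMIs), Oit3 (-6.21), Stab2 (-6.14), Ehd3 (-6.06), Cyp26b1 (-5.76) and Gpr182 (-5.68) followed, with the mast cell and basophil protease gene Prss34 (-6.04) and the granule protease gene Prtn3 (-5.56). Sftpc, a lung surfactant gene (chromosome 14, 70520949 to 70524081, minus strand), was highest in YO2 with the same pseudocount at 7.39 (7.15 to 7.61; 26 and 11463 UMIs). The surfactant gene Sftpa1 (5.87), the lung chemokine gene Cxcl15 (5.68), the gut gene Lypd8 (5.13) and the immunoglobulin genes Iglc1 (5.98), Ighg3 (5.63), Igkv8-27 (5.13), Iglv1 (5.08), Igkj1 (4.83) and Igkv9-124 (4.81) were the others. In cells, 96.2% of the Clec4g UMIs of YO1 lay in cluster 13, 97.3% of its Elane UMIs in cluster 14, and 98.6% of the Sftpc UMIs of YO2 in cluster 28. The ratios depended on the pseudocount. With 10 CPM all 20 were closer to 0 and their order changed, Clec4g (-4.72), Elane (-4.65) and Ehd3 (-4.56) lying below Mpo (-4.51), and Iglc1 (5.44) above Sftpc (4.75). The counts then fell to 19 in YO2 and 51 in YO1, and with 1 CPM and a minimum of 500 UMIs 58 were higher in YO2.

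**Figure D3:**
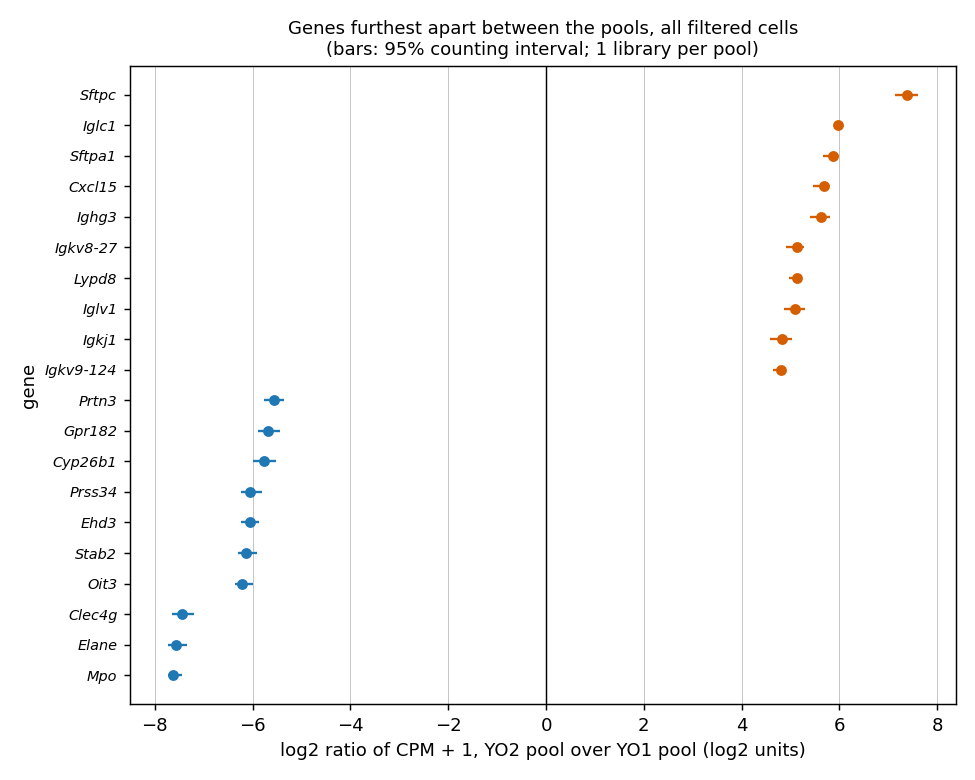
Log2 ratio of CPM, YO2 over YO1, of the 10 genes highest and the 10 lowest among 11681 genes, with a pseudocount of 1 CPM and 95% counting intervals. The ratios run from -7.63 (Mpo) to 7.39 (Sftpc), which became -4.51 and 4.75 with 10 CPM.

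Over all cells, the median log2 ratio of YO2 to YO1 was -4.70 for primary granule, -1.94 for secondary granule, -1.94 for cell cycle and -0.78 for NADPH oxidase and antimicrobial genes, and -0.25 for tertiary granule genes. It was 0.78 for NF-kB response, 0.65 for immediate early, 0.34 for interferon-stimulated, 0.36 for apoptosis and survival and 0.79 for MHC class II genes. Medians over all cells do not separate the mix of clusters in a pool from changes within clusters. Trafficking (0.26), senescence (0.31), angiogenesis (0.22), phagocytosis (0.15), circadian clock (0.13), lipid handling (0.12), heat shock (0.04), MHC class I (0.04), sex-linked (0.04), ribosomal (0.00) and mitochondrially encoded genes (0.08) lay close to or above 0, and glycolysis (-0.23) and oxidative phosphorylation (-0.21) below it. Of the cell type lists, the markers of plasma cells (2.82), epithelial cells (1.73), B cells (1.04), dendritic cells (0.75), T cells (0.53), monocytes (0.29) and tissue macrophages (0.18) were higher in YO2. Those of endothelial cells (-2.85), eosinophils (-2.34), stromal cells (-2.10), NK cells (-1.53), stem cells (-1.15), basophils or mast cells (-0.76) and platelets (-0.64) were higher in YO1. Such medians need not follow the shares of cells. Cluster 23, named as T cells, held 0.723% of YO1 and 0.453% of YO2, and monocyte cluster 9 held 4.46% and 3.18%. Among lists of neutrophil stages and of cycling cells, primary-granule progenitor (-4.20), cycling (-2.09), secondary-granule (-2.05) and late immature markers (-0.96) were higher in YO1, and activated (0.83), interferon-stimulated (0.35) and mature markers (0.27) in YO2. Of the erythroid and hepatocyte lists 2 genes each had enough UMIs, so no median was taken.

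The pools were also compared within clusters. Between 2 and 10 genes were at least 4-fold higher in YO2 and between 1 and 6 in YO1 in each of the neutrophil clusters 1, 2, 3, 4, 6 and 7, which had at least 400 cells per pool, a minimum set after the data were seen. Outside these, cluster 8 had 104 genes at least 4-fold higher in YO2 and 6 in YO1 of 3235, and cluster 14 had 18 and 91 of 6027. In the 6 clusters, 5 of 3229 genes were at least 2-fold higher in YO2 in every one, and 0 were so in YO1. Among the 3229 genes, the mean log2 over clusters had a list median of 0.05 for NF-kB response genes (cluster medians -0.16 to 0.60). It was 0.16 for immediate early genes (-0.28 to 1.14), so clusters differed in both lists. For interferon-stimulated genes it was -0.05 (-0.06 to 0.38), for apoptosis and survival 0.07 (-0.07 to 0.28) and for MHC class II 0.47 (0.17 to 0.56). Secondary granule genes stood at -0.24 (-0.38 to -0.07) and NADPH oxidase and antimicrobial genes at -0.21 (-0.29 to -0.10). With numbered gene models, ribosomal and mitochondrially encoded genes left aside, the largest means were those of Igha (4.21, range over clusters 3.49 to 4.43; chromosome 12, 113254830 to 113260236, minus strand), Jchain (3.05) and Igkc (3.02, 1.73 to 3.86), followed by the immediate early gene Egr1 (1.96, 0.24 to 3.12), the enolase gene Eno1 (1.53, 1.21 to 1.99), Taf7 (0.97), Acadm (0.94), Dnajb9 (0.84), Slc39a1 (0.75) and the cytokine gene Osm (0.73). Genes higher in YO1 were Ngp (-1.66, -2.39 to -0.01), the inducible heat shock gene Hspa1b (-1.47, -3.21 to -0.10), Ier3 (-0.82), Chil3 (-0.80), Palm (-0.78), H2afj (-0.73, -0.87 to -0.51), Smdt1 (-0.73), Acly (-0.66), Mdh2 (-0.65) and Myl12b (-0.62). Mean CPM of Ngp over the clusters was 9588 in YO1 and 9353 in YO2, so its mean log2 reflects clusters with less Ngp. Free RNA was not tested as a source of that difference.

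Immunoglobulin transcripts were found in most YO2 cells of each cluster with at least 30 cells in that pool. At least 1 Igkc UMI was seen in 64.6% of cells in the neutrophil clusters of YO2 and in 8.46% of those of YO1. T cells, which do not make immunoglobulin, had Igkc UMIs in 83.3% of cells in YO2 (median depth 3005 UMIs) and 5.67% in YO1 (1554 UMIs). Cluster 1 had them in 60.8% of YO2 cells (1179 UMIs), cluster 7 in 85.1% (4330 UMIs) and the monocytes of cluster 9 in 86.1% (4747 UMIs). In YO2 the shares in neutrophils lay at or below those in T cells or followed depth. In YO1 the neutrophil share of 8.46% lay above the 5.67% of its 141 T cells. These shares are not reported as expression by neutrophils. Plasma cells of YO2 held 95.7% of its Igkc UMIs.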

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

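The tests of depth, of tissue mix, of a dissociation response of doublets in cluster 8, and of doublets with plasma cells in most cells were chosen only after the result was seen, and those of free RNA and of the cells with the most Igkc were written before. In cluster 8 against cluster 1, the median changes of 5 lists with at least 3 genes passing had opposite signs in the pools. The YO2 median minus the YO1 median was 0.36 for apoptosis and survival, 0.18 for glycolysis, 0.57 for immediate early, 1.15 for lipid handling and 0.48 for oxidative phosphorylation genes. In cluster 14 it was 0.40 for NADPH oxidase and antimicrobial genes, -0.41 for heat shock and -0.60 for senescence genes. Barcodes left out of the analysis held 1.29% of their UMIs in S100a8 and S100a9 in YO1 and 0.580% in YO2. These differences were not tested.

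Endothelial-like cluster 13, with Clec4g, Stab2 and Oit3, was nearly confined to YO1. With an equal minimum of UMIs the share was 161-fold higher in YO1. That minimum cannot decide on depth, because at most 547 cells of YO1 fell below it while cluster 13 held 892. The YO1 cells of cluster 13 had a median of 2415 UMIs, and the smallest kept cell of YO2 had 496. The higher minimum of YO2 alone therefore cannot account for the near absence of such cells there. Other effects of depth were not tested. Free RNA did not account for it, because 96.6% of the UMIs of these 3 genes in YO1 lay in the cells of cluster 13. A different mix of tissues stays open. The hepatocyte list fold of 1.39 decides nothing: Hp, also a neutrophil granule gene, held 48239 of its 48555 UMIs in YO1. All 12 genes of that list were higher in YO1, but Hp aside none had more UMIs than Alb (164 and 0). The epithelial list was 1.51-fold higher in YO2, with 12 genes higher there and 4 higher in YO1. Its gene Fabp1 (825 and 1396 UMIs) was also a leading gene of macrophage cluster 12, which was not left out. A different mix would give such directions, but low counts and shared genes do not establish it. Age or another biological difference between the rounds was not tested.

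Immunoglobulin UMIs lay in the neutrophil clusters of YO2. Doublets with plasma cells did not account for most of these cells, since 64.6% of the cells in those clusters held Igkc UMIs while plasma cells made up 2.26% of YO2. Doublets stay open for the cells with the most, because the highest 1% of cells held 26.1% of the Igkc UMIs, between the limits of 10% and 50%. Free RNA from plasma cells stays open too, since the largest departure of log2 Igha over Igkc from its median was 0.957, between the limits of 0.5 and 1. That departure came from cluster 14 (-2.08, 69 cells of YO2). The other neutrophil clusters of YO2 lay between -1.46 and -0.81 around the median of -1.13, and its plasma cells stood at -0.86. Its clusters of other cell types, B cells and plasma cells aside, lay between -1.27 (cluster 22) and -0.72 (cluster 28). T cells stood at -0.84, so such a ratio was not particular to neutrophils. Uptake of plasma cell material by neutrophils was not tested.

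Activated cluster 8, with Il1a, Cxcl2 and Icam1, came mostly from YO2. At an equal minimum of UMIs its share was 15.9-fold higher in YO2. That minimum took cells only from YO1, which held 98 cells of cluster 8, so it cannot decide on depth. The smallest kept cell had 200 UMIs in YO1 and 496 in YO2, so the minimum of YO1 alone cannot account for its few cells. Other effects of depth were not tested. Doublets stay open too, because the Scrublet threshold marked 0 cells in YO1 and 4 in YO2. The 6.95% of cluster 8 among the highest scores stands against a set fixed at 5% of each pool. A dissociation response could not be told apart, since the lowest median of immediate early genes in the macrophage clusters was 0.29 while heat shock genes were not higher in all of them. Tissue and age, which could also give such a cluster, were not tested.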

How the results depend on the processing

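Of the values of named genes under alternatives other than the omission of a sum, 1244 kept their side of the threshold, 59 lost their call and 5 gained one. A change of direction was counted only where the gene passed in the main or the alternative setting. With a sum left out, 524 kept their side, 62 lost their call and 2 reversed. Without the YO2 sum of cluster 8, Ccng1 was -0.61 and Bax -0.30, while without the YO1 sum they were 1.33 and 1.68. The alternatives without low-count filter, with clusters made on a split of the UMIs, without the highest doublet scores, with an equal minimum of UMIs, and with a sum left out were added after the data were seen. The settings meant for ages, tissues, their interaction, class shares by tissue and antibody-oligo values were not run, and the one on cells marked by Scrublet was replaced by the highest 5% of scores. Where no reason is given, the cause was not tested.

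The share of neutrophil clusters was 66.5% in YO1 and 74.0% in YO2 with all deposited barcodes, and in YO1 76.0% when thinned to 500 UMIs and 76.4% without the highest doublet scores. Of clusters 4, 5, 7, 8, 13, 14, 15 and 18, matched by overlap, the pool with the higher share was the same in every setting, but some shares moved by over 1.5 times. In YO1 and YO2, cluster 7 held 3.80% and 0.953% at resolution 1.5, 4.24% and 1.10% with split UMIs, and 909 and 206 cells, 4.79% of YO1, with an equal minimum. Cluster 4 held 3.55% and 5.23% with an equal minimum and 3.65% and 5.43% with at least 500 UMIs and 250 genes. Cluster 5 held 6.74% and 0.444% without the highest doublet scores, cluster 8 held 0.282% of YO1 with split UMIs, and cluster 13 had 0 cells of YO2 at resolution 1.5 and without the highest doublet scores.

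For cluster 3, genes higher and lower were 135 and 32 with all deposited barcodes, but the clusters matched to clusters 3 and 1 shared only 0.279 and 0.471 of the joined cells with them, so other cells were largely compared. Cluster 3 had no match with split UMIs or without the highest doublet scores, and no value there. The counts were 11 and 4 when thinned, and 15 and 4 without the low-count filter. DESeq2 called 14 higher. Without the block, with the mean over cells in limma, and with each sum left out in edgeR, 0 were higher and 0 lower, and with total UMIs 0 were higher.

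For cluster 4, 61 were higher with total UMIs, 49 without the block, 20 with the mean over cells, and 34 to 67 with a sum left out. There were 0 lower with all of these except total UMIs, and 0 with DESeq2, all barcodes, thinning, split UMIs and no highest doublet scores; 1 was lower without the low-count filter.

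For cluster 5, 808 were higher and 2281 lower with total UMIs, 832 and 654 when thinned, 766 and 486 with split UMIs. The mean over cells gave 419 higher. With a sum left out, 435 to 1410 were higher and 193 to 768 lower, the lowest when 138 cells of YO2 were left. For cluster 7, 1310 were higher and 1196 lower when thinned, and 1015 higher with the mean over cells. For cluster 8, 676 and 680 without the block and 424 and 673 with the mean over cells were higher and lower, with 682 higher when thinned and 707 lower with DESeq2. With a sum left out, 49 to 1302 were higher and 65 to 989 lower. For cluster 14, 1707 were higher and 1587 lower when thinned, 1528 lower with the mean over cells, and 2004 to 3689 higher with a sum left out, 2004 without the YO1 sum of cluster 14. Thinning tested fewer genes.

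Camera with an estimated correlation passed 0 lists in each of the 6 contrasts, against 5, 7, 8, 5, 7 and 11 with the preset one for clusters 3, 4, 5, 7, 8 and 14. Fry passed 2, 1, 11, 10, 8 and 15 for the same clusters.

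Between the pools, 51 genes were at least 4-fold higher in YO1 and 19 in YO2 with a pseudocount of 10 CPM, and 58 in YO2 with a minimum of 500 UMIs. The 20 named ratios were all closer to 0 with 10 CPM, Mpo at -4.51 and Sftpc at 4.75.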

Other observations

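Clusters 2, 6 and 10 scored highest on neutrophil lists but met no naming rule. Cluster 2, with Trem1, Cd14 and Ptgs2, held 13.3% of YO1 and 15.2% of YO2, and cluster 6, with Taf7 and Egr1, held 2.18% and 9.88%. Cluster 10, with Ier3 and the mitochondrially encoded mt-Nd2, mt-Nd3, mt-Nd4, mt-Nd4l and mt-Nd5 among its leading genes, held 5.27% and 1.76%. The female-specific transcript Xist had 4 UMIs in YO1 and 13 in YO2, and the Y-linked gene Ddx3y had 3000 and 3747. Eno1 stood at 55.5 CPM in YO1 and 122 CPM in YO2, and the related gene Eno1b at 4.56 CPM and 3.90 CPM. Barcodes left out had a median of 193 UMIs in YO1 and 836 in YO2, with 50.9% and 51.3% of UMIs from mitochondrial genes.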
